A study of Glycine max with 12 samples.

How the data were processed

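RNA was sequenced from leaves and roots of soybean (Glycine max) plants that overexpress GmZF351, a tandem CCCH zinc finger gene, and from control plants of the cultivar Jack. Per the labels, the plants of transgenic line OE-34 and of Jack grew in pots and were sampled at the V1 stage, when their first trifoliate leaf had opened fully. Total RNA was isolated with TRIzol and made into standard Illumina libraries, per the labels' protocols. The 12 libraries form 4 groups of 3, called OE leaf, WT leaf, OE root and WT root here, with WT standing for Jack. The labels call the replicates biological repeats and say nothing more about plants or pools, so p-values measure the spread between these samples.

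The deposited table holds unnormalised read counts per gene model, made by the authors with featureCounts v2.0.1 over exons grouped by gene identifier in paired-end mode with 4 threads, per the file headers. The annotation was Wm82.a2.v1, per the file headers, and all coordinates are those of that annotation. The aligner is not given in the sources used here. The recorded command sets no strand option and asks for neither multi-mapping nor multi-overlapping reads, so reads from a gene and from an antisense partner cannot be told apart. Under these settings reads shared by near-identical copies are not counted, which lowers the counts of young duplicates. Soybean has many such pairs, and the values of CHS7 and CHS8, IFS1 and IFS2, and the LHY copies are uncertain for this reason.

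The table lists 43517 gene models, 43251 of them on the 20 chromosomes and 266 on scaffolds, and 2068 had no count in any library. Libraries held 16885874 to 19041634 counts. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per gene between 2.26 and 9.87 over genes with at least 50 counts in the pair, so none was treated as a repeat deposit. A count of 0 in a library allows up to 3 counts, the floor used for lower bounds of folds, per library. Intervals of the GmZF351 ratios are 95% exact binomial (Clopper-Pearson) intervals, and these and the floors cover counting error only.

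Counts were analysed in R 4.3.3 with edgeR 4.0.16. TMM factors scaled the libraries, and filterByExpr on the 4 groups kept 35968 genes, which hold 99.94% of all counts. One robust quasi-likelihood model with a coefficient per group was fitted to all 12 libraries, leaving 8 residual degrees of freedom, and its common biological coefficient of variation was 0.094. From it came OE against WT in leaf, OE against WT in root, the difference of these effects (root minus leaf) and WT root against WT leaf. Adjusted p-values are edgeR quasi-likelihood p-values with Benjamini-Hochberg adjustment over all genes tested, and genes with adjusted p under 0.05 are called changed. Levels are CPM on TMM-scaled library sizes, given as mean ± SD, and standard errors (SE) belong to the log2 fold change (log2FC) of the model. TMM factors were 0.862 to 0.889 in OE leaf and 0.665 to 0.676 in WT leaf, and 1.345 to 1.352 in OE root and 1.249 to 1.276 in WT root, so fold changes, in leaf most of all, are relative to the bulk of the genes and not to the total count.

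The fit was tested on simulated data, with counts drawn from the real library sizes and dispersions and from tissue means pooled over genotypes. At each of 4 fold sizes 50 genes were changed, with rises and falls in equal number and genes of low counts left out. Far fewer genes were changed than the real comparisons called, 40.4% of genes in leaf and 30.1% in root. The shares and false calls below therefore need not hold for the real data. For the leaf comparison, run on 35669 genes, 6% of genes changed 1.25-fold were recovered, 54% at 1.5-fold, 78% at 2-fold and 100% at 4-fold, with 8 false calls among 127. For the root comparison, run on 35673 genes, the shares were 18%, 56%, 86% and 98%, with 6 false calls among 135.

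The symbol table used for names belongs to assembly Glycine_max_v4.0, carries no gene descriptions and matched 0 of the 43517 identifiers. The gene lists planned as searches of descriptions were therefore not applied. In their place, 120 gene identifiers with published names were written down from general knowledge, 19 of them before the data were examined and 101 later, before any fold change was computed. A name was kept where exactly 1 gene on the same chromosome of the symbol table had a symbol or listed synonym that matched the name's pattern and the genomic span of that gene was within 10%, which left 74 names, 15 and 59 of them. The counts of 3 of the later ones (LOX4, RBCS2 and RCA11) had been seen before they were written. Some names, such as LHY2b (main symbol MYB114) and LOX4 (LOXB1), matched through a synonym. A name rests on this match and not on a shared identifier. The patterns for matching symbols were narrowed after the first pass, before these genes' fold changes were looked at. The groups, comparisons, the model and set tests, the alternatives, the rule for named genes and the 19 identifiers were fixed before the data were examined, whereas the members of the gene sets and the tests of close gene pairs and of length as the whole cause were not.

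Under that rule, text names GmZF351 and the known genes, and at most 2 rising and 2 falling genes without a name per comparison. In each tissue these come from the largest log2FC among called genes with a mean of at least 5 CPM and no overlap between genotypes. For genes called in both tissues the rule ranks the smaller of the 2 absolute log2FC values, for the difference between tissues the adjusted p, and for the tissue comparison the expression level. Sets of known genes with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over sets and tissues. Overlaps were tested with a two-sided Fisher's exact test over genes, which also gave the intervals of the odds ratios.

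Alternatives were DESeq2 size factors in the edgeR fit, no count filter (41449 genes), a filter of 1 CPM in at least 3 libraries (34359 genes), DESeq2 1.42.0 in place of edgeR, fits on the libraries of a single tissue, a replicate block, each library left out in turn, a minimum of 2-fold change, and glmTreat in edgeR against a log2FC of 0.5. For the gene sets they were a correlation estimated per set, and fry. The gene sets named by identifier were added after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for the remaining tests and the plots.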

Results

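Leaf and root transcriptomes of soybean line OE-34, which overexpresses the zinc finger gene GmZF351, were compared with those of the control cultivar Jack (WT) at the V1 stage, with 3 libraries per genotype and tissue. Library totals ran from 16892076 to 19041634 counts in OE leaf, 17947388 to 18326987 in WT leaf, 17801820 to 18686319 in OE root and 16885874 to 17330102 in WT root. Between 36459 and 36586 genes had a count in OE leaf libraries, 35947 to 36173 in WT leaf, 37857 to 37936 in OE root and 37179 to 37723 in WT root. The 10 most abundant genes took 6.84% ± 0.26 of counts in OE leaf, 8.7% ± 0.32 in WT leaf, 3.74% ± 0.09 in OE root and 3.54% ± 0.21 in WT root (SD, n = 3). The first principal component held 90.7% of the variance and the second 4.3%. Among root controls, WT root replicate 3 stood apart, with a chi-square per gene of 9.87 against replicate 1 and 7.1 against replicate 2, where replicates 1 and 2 gave 2.97.

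GmZF351 (Glyma.06G290100, chromosome 6, 47897433 to 47899059, minus strand, 1 exon of 1627 bp) encodes a CCCH zinc finger protein known for raising seed oil, and its transcript was abundant in each OE library and nearly absent from WT. It reached 2296 ± 132.7 CPM in OE leaf and 1355 ± 65.1 CPM in OE root (SD, n = 3), and ranked 26 among all genes in OE leaf and 14 in OE root. The 3 WT leaf libraries held 1 GmZF351 count in all and the 3 WT root libraries 4. The ratio OE over WT was 83800 in leaf, with a 95% exact counting interval of 15000 to 3310000, and 21900 in root, with an interval of 8550 to 80300. edgeR gave adjusted p = 3.31e-31 in leaf and 3.16e-31 in root. Counts per gene model do not separate transcripts of the introduced copy from those of the resident gene.

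**Figure D1:**
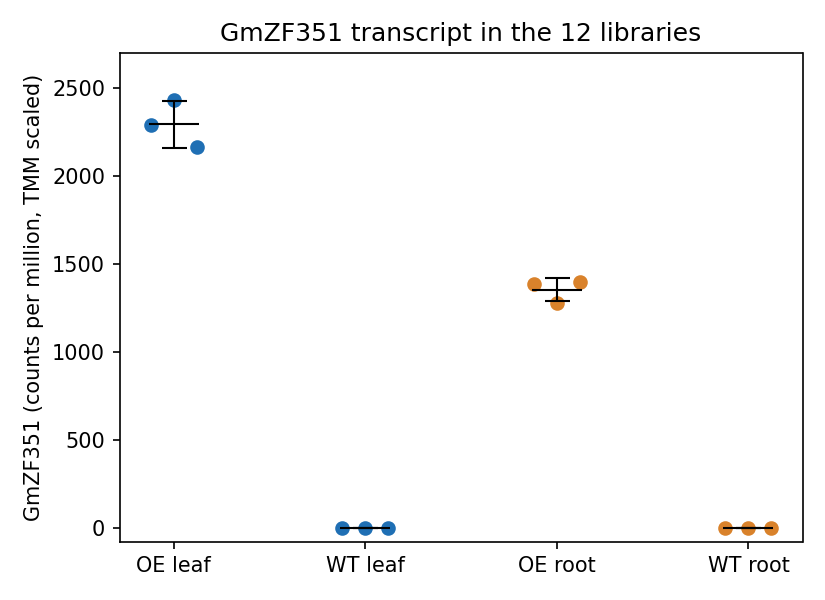
GmZF351 transcript level per library in TMM-scaled CPM (linear y axis) for OE and WT in leaf and root, with points for the 3 libraries of each group and black lines for their mean and SD. OE libraries lie around means of 2296 CPM in leaf and 1355 CPM in root, and the WT libraries, with 1 and 4 counts per tissue, lie at the bottom of the axis.

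The leaf comparison asks which transcripts differ when GmZF351 is overexpressed in an expanded leaf. Both florigen genes measured were far lower in OE leaf. FT5A (Glyma.16G044100, chromosome 16, 4135885 to 4137742) stood at 1.045 ± 0.348 CPM against 53.03 ± 6.67 in WT, 50.6-fold lower (log2FC -5.66, SE 0.213, edgeR adjusted p = 2.1e-20). FT2A (Glyma.16G150700, chromosome 16, 31109999 to 31114963) stood at 1.471 ± 0.462 against 18.58 ± 0.703 CPM (SD, n = 3), 12.7-fold lower (log2FC -3.66, SE 0.242, edgeR adjusted p = 4.23e-13). The clock gene GIa (Glyma.10G221500, chromosome 10, 45294735 to 45316121), the soybean GIGANTEA gene of maturity locus E2, rose 2.78-fold, from 23.87 ± 0.824 to 66.48 ± 2.48 CPM (log2FC 1.48, SE 0.105, edgeR adjusted p = 2.49e-13). The phytochrome A genes PHYA1 and PHYA2, red and far-red light receptors, rose by log2FC 0.94 (SE 0.0968) and 0.95 (SE 0.0895), the clock gene PRR3B by 1.30 (SE 0.175) and the blue light receptor gene CRY2a by 0.45 (SE 0.0833). LHY1a (Glyma.16G017400), a morning-phased clock repressor, had log2FC -0.27 (SE 0.0784, edgeR adjusted p = 0.00671). Of the 18 clock and flowering genes tested, 5 rose and 5 fell in leaf, and 11 passed when adjusted over the list alone. The set had no common direction (camera adjusted p = 1, and 1 with an estimated correlation). Its median of -0.13 and mean of -0.40 lay below 0 while camera's statistic pointed up. The florigen repressor E1 fell on low counts (log2FC -1.57, SE 0.548, edgeR adjusted p = 0.023), and LHY2b fell by 0.20 on the log2 scale. Leaving out OE leaf replicate 2 or 3 or WT leaf replicate 1 or 3 ended both calls, with edgeR adjusted p up to 0.0917 for E1 (without WT leaf replicate 3) and 0.175 for LHY2b (without OE leaf replicate 2).

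Lipoxygenase genes, whose enzymes oxidise polyunsaturated fatty acids, fell in leaf for 3 of 3 tested members, all written down after the data were examined. The members planned before that, LOX1, LOX2 and LOX3, had 0 counts in leaf and at most 5 per genotype in root. They were not tested, so the count does not cover the whole family. LOX4 (Glyma.13G347700, chromosome 13, 43773475 to 43780320) went from 2079 ± 115 CPM in WT to 484.9 ± 23.3 in OE, 4.29-fold lower (log2FC -2.10, SE 0.0828, edgeR adjusted p = 5.26e-20). LOX10 (Glyma.08G189600, chromosome 8, 15235197 to 15239971) went from 31.69 ± 1.97 to 1.406 ± 0.358 CPM, 22.6-fold lower, and LOX7 (Glyma.13G347800) from 72.96 ± 2.8 to 14.54 ± 0.45 CPM (SD, n = 3). Vegetative storage protein genes, which encode leaf nitrogen stores of the acid phosphatase family, fell for 2 of 2 members. VSPA (Glyma.07G014500, chromosome 7, 1145046 to 1146554) went from 1014 ± 69.6 to 199.5 ± 14.3 CPM, 5.08-fold lower (log2FC -2.35, SE 0.103, edgeR adjusted p = 6.94e-17), and VSPB from 59.99 ± 11.7 to 21.98 ± 6.07 CPM. The Rubisco small subunit gene RBCS2 (Glyma.19G046800) and the Rubisco activase gene RCA11 (Glyma.11G221000) fell as well. RBCS2 was at 6515 ± 1000 CPM in OE and 13640 ± 1770 in WT, 2.09-fold lower, and RCA11 at 15310 ± 687 and 25970 ± 1160 CPM, 1.7-fold lower. RBCS2, RCA11 and LOX4 were chosen after their counts had been seen.

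Genes of oil synthesis went both ways in leaf, where 2 of 10 tested members rose and 2 fell, with 5 passing when adjusted over the list alone. The thioesterase gene FATB1a, whose enzyme releases saturated fatty acids, rose from 47.74 ± 2.92 to 72.87 ± 4.12 CPM (log2FC 0.61, SE 0.0865, edgeR adjusted p = 6.85e-07). The oleate desaturase gene FAD2-2B rose from 695.8 ± 16.5 to 959.8 ± 52.6 CPM (log2FC 0.46, SE 0.0794), and the linoleate desaturase gene FAD3C fell from 226 ± 12.8 to 177.5 ± 5.95 CPM (log2FC -0.35, SE 0.086). FAD3A had log2FC -0.38 (edgeR adjusted p = 0.013), which ended without OE leaf replicate 1 or without OE leaf replicate 3, where the adjusted p was 0.127. WRI1A, a regulator of fatty acid synthesis, had log2FC -0.78 in leaf (edgeR adjusted p = 0.0956) and WRI1B 0.07 (0.967), and the acyltransferase gene DGAT1A had -0.09 (0.706), none past the threshold. The set showed no common direction (camera adjusted p = 0.99, and 0.98 with an estimated correlation), with a median of -0.17 and a mean of -0.10 where camera's statistic pointed up. Of 12 flavonoid genes, 3 rose and 2 fell in leaf, and 5 passed when adjusted over the list alone. IFS2, an isoflavone synthase gene, fell 3.13-fold, from 69.62 ± 6.16 to 22.23 ± 1.0 CPM (SD, n = 3), and the phenylalanine ammonia-lyase gene PAL1.1 fell with log2FC -0.84 (SE 0.092), while the flavonol synthase gene FLS1 rose by 0.32 (SE 0.0916). The flavonoid set had no common direction in leaf (camera adjusted p = 0.99, and 0.98 with an estimated correlation), its median being 0.10 and its mean -0.30.

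In leaf as a whole, 14544 of 35968 genes (40.4%) passed adjusted p under 0.05 in edgeR, 6596 up and 7948 down. Their median absolute log2FC was 0.71. At least 2-fold changes numbered 4429, with 1759 up and 2670 down, and at least 4-fold changes 1355, with 384 up and 971 down. Among genes without a name, Glyma.08G158200 (chromosome 8, 12254113 to 12256668) rose from 0.22 ± 0.048 to 19.64 ± 1.35 CPM, 86.9-fold, from 8 counts in WT leaf in all. Glyma.18G103500 (chromosome 18, 11234541 to 11236613) had no count in OE leaf and 3330 to 3505 counts per WT leaf library, at least 1490-fold lower against the floor of 3 counts per library. Glyma.12G184400 (chromosome 12, 34559090 to 34566079) likewise had none in OE leaf and 928 to 1079 per WT library, at least 437-fold lower.

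The root comparison asks the same of roots. Of the flavonoid genes called there, each was lower in OE root. CHS7 (Glyma.01G228700, chromosome 1, 55659010 to 55660950), a chalcone synthase gene at the entry of the pathway, went from 961.4 ± 29.1 CPM in WT root to 416.1 ± 23.6 in OE root, 2.31-fold lower (log2FC -1.21, SE 0.0853, edgeR adjusted p = 3.19e-13). CHS8 (Glyma.11G011500) went from 629.2 ± 17.6 to 305.4 ± 20.5 CPM, and the isoflavone synthase genes IFS1 (Glyma.07G202300) and IFS2 (Glyma.13G173500, chromosome 13, 28761503 to 28763755) from 828.3 ± 55.2 to 608.1 ± 7.14 and from 254.5 ± 19.9 to 137.5 ± 6.48 CPM (SD, n = 3). PAL1.1 had log2FC -1.03 (SE 0.0849) and the chalcone isomerase gene CHI1A -0.34 (SE 0.0857). Of 12 flavonoid genes tested in root, 7 fell and 0 rose over all genes tested. When adjusted over the list alone, 8 passed, the added one being FLS1, which was higher in OE root on 17 counts against 5 (2.82-fold, SE 0.663 on the log2 scale, edgeR adjusted p = 0.0875 over all genes and 0.0464 over the list). Camera gave the set an adjusted p of 0.00062 downward, and 0.021 with an estimated correlation, with a median log2FC of -0.45. The seventh, the regulator MYB176, fell by 0.23 on the log2 scale. Its call ended without replicate 1 or 2 of either genotype, with edgeR adjusted p up to 0.0915 (without OE root replicate 1).

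Clock genes moved in root too. The 4 LHY genes, morning-phased repressors of the clock, were higher in OE root, with log2FC 0.40 (SE 0.0788) for LHY1a, 0.38 (SE 0.0843) for LHY1b, 0.47 (SE 0.0823) for LHY2a and 0.76 (SE 0.0808) for LHY2b, whose edgeR adjusted p was 4.19e-09. GIa rose 2.28-fold, from 20.76 ± 3.43 to 47.4 ± 4.04 CPM (log2FC 1.19, SE 0.101, edgeR adjusted p = 2.54e-11). ELF3A, a gene of the evening complex of the clock, fell by 0.59 on the log2 scale (SE 0.128) and PHYA3 by 0.76 (SE 0.15). Of 18 clock and flowering genes, 7 rose and 5 fell, and 13 passed when adjusted over the list alone. Camera gave the set an adjusted p of 0.13, and 0.71 with an estimated correlation, whereas fry, which does not compare the set with other genes, gave 0.014. The set's median was 0.06 and its mean -0.10. The call of FT5A in root, on few counts, ended without OE root replicate 1, WT root replicate 2 or WT root replicate 3, with edgeR adjusted p up to 0.127 (without the last). That of LUXC ended without OE root replicate 2 or 3 or WT root replicate 1 or 2, with adjusted p up to 0.15 (without OE root replicate 3).

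LOX4 fell 1.6-fold in root, from 3486 ± 163 to 2174 ± 40.6 CPM, and LOX7 had log2FC -1.52 (SE 0.155), while LOX10 had -0.09 (edgeR adjusted p = 0.655). Of the lipoxygenase genes tested, 2 of 3 thus fell. VSPB fell from 17.61 ± 0.601 to 4.488 ± 0.755 CPM, and 1 of 2 vegetative storage genes fell. Of the 10 oil genes, 1 rose in root and 0 fell, and 1 passed when adjusted over the list alone. It was the stearoyl-ACP desaturase gene SACPD-C, at 21.64 ± 0.924 CPM in OE and 14.73 ± 2.05 in WT (log2FC 0.56, SE 0.134, edgeR adjusted p = 0.00175). The oil set gave camera adjusted p = 0.99, and 0.98 with an estimated correlation. Of the pair of Rubisco genes 0 passed, with log2FC -0.02 for RBCS2 (edgeR adjusted p = 0.959) and -0.22 for RCA11 (0.41).

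**Figure D2:**
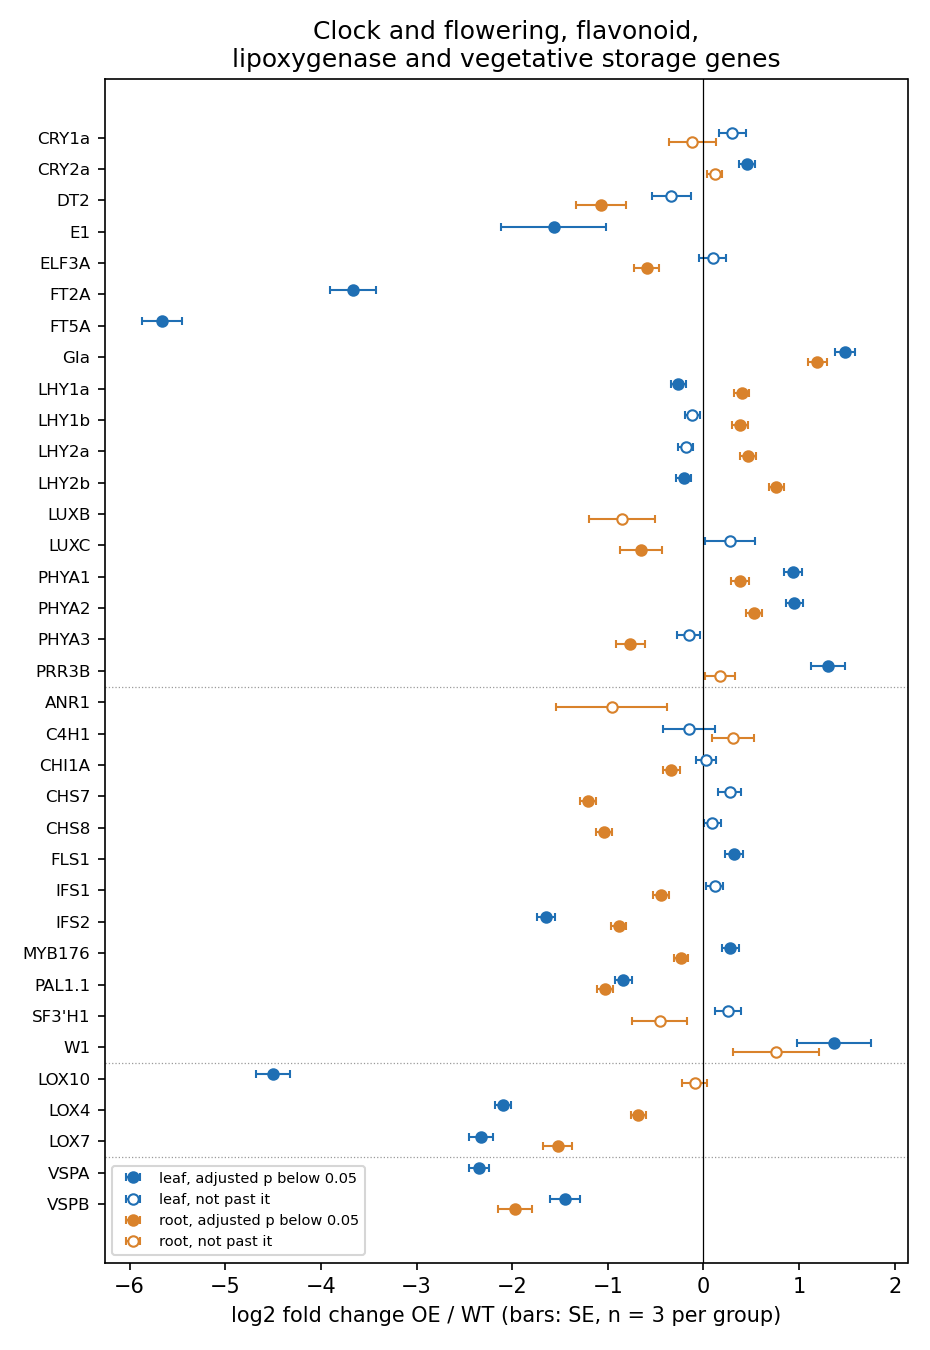
Log2 fold change of OE over WT (x axis) for clock and flowering, flavonoid, lipoxygenase and vegetative storage genes in leaf and in root, for pairs of gene and tissue with at least 10 counts in each genotype, with bars of 1 SE and filled points for edgeR adjusted p under 0.05. FT5A at -5.66 in leaf, LOX10 at -4.50 in leaf and CHS7 at -1.21 in root lie to the left, and GIa at 1.48 in leaf and 1.19 in root lies to the right.

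In root, 10822 of 35968 genes (30.1%) passed adjusted p under 0.05 in edgeR, 4310 up and 6512 down, with a median absolute log2FC of 0.6. At least 2-fold changes numbered 2710, with 725 up and 1985 down, and at least 4-fold changes 760, with 144 up and 616 down. Glyma.15G245300 (chromosome 15, 46683513 to 46689035) rose from 2.225 ± 0.31 to 37.48 ± 0.597 CPM, 16.8-fold (log2FC 4.07, SE 0.157, edgeR adjusted p = 4.04e-20), and had log2FC -1.63 in leaf. Glyma.20G129000 (chromosome 20, 37038318 to 37040153) fell 536-fold, from 69.09 ± 0.809 to 0.122 CPM, a fold that rests on 9 counts in OE root in all and is imprecise. Without WT root replicate 3, the root control that stood apart, 9341 genes passed in root. Leaving out any other single root library lowered the count as well, to between 8421 and 10057, so the drop is not particular to that replicate.

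Whether the same genes moved in both tissues was tested on the called genes, which have separate control libraries in leaf and root. Both lists nevertheless come from a single fit that shares a dispersion per gene, and genes are not independent replicates. The shared counts given for independent lists and the intervals of the odds ratios are therefore rough. Both tissues called 5724 genes, and 4626 of these (80.8%) went the same way. Of them, 1586 rose in both, where independent lists would share 790.4 (odds ratio 3.1, 95% interval 2.89 to 3.32), and 3040 fell in both against 1439 (odds ratio 4.38, interval 4.13 to 4.64). At 4-fold or more, 187 genes fell in both tissues where 16.6 would be shared (odds ratio 19.2, interval 15.9 to 23.2), and 20 rose against 1.5 (odds ratio 15.7, interval 9.17 to 25.7). Glyma.12G184400, absent from OE leaf, fell 83.1-fold in root (log2FC -6.38, SE 0.146, edgeR adjusted p = 4.48e-25). Glyma.03G032400 (chromosome 3, 3694048 to 3698244) fell 354-fold in leaf and 465-fold in root. These folds rest on 4 counts in OE leaf and 14 in OE root in all, so they are imprecise. Glyma.18G226300 (chromosome 18, 51471540 to 51498344) rose 64.1-fold in leaf, from 15 counts in WT leaf in all, and 16.1-fold in root. Across genes, which are not independent replicates, the leaf and root log2FC correlated with Pearson r = 0.31 and Spearman rho = 0.29.

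**Figure D3:**
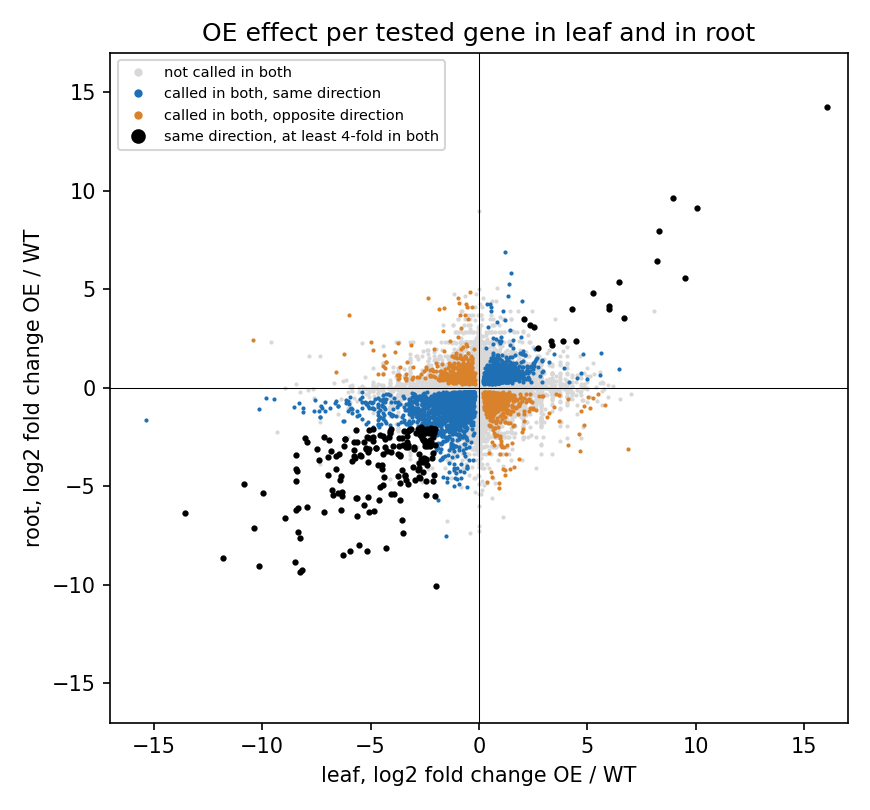
Log2 fold change of OE over WT in leaf (x axis) against root (y axis) for all tested genes, in blue where called in both tissues in the same direction, black where such a change was at least 4-fold in both, orange where called in opposite directions and grey otherwise. Of the 5724 genes called in both, 4626 lie in the quadrants of equal sign and 1098 in the others.

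The difference of the OE effect between root and leaf was tested directly and passed for 8198 genes (22.8%) in edgeR, 4167 with the higher log2FC in root and 4031 in leaf. This balance depends on the scaling, with 4891 and 3432 under DESeq2 size factors, and it turned to 3585 and 3727 without OE leaf replicate 3. For LOX10 the effects differed, the root effect exceeding the leaf effect by 4.41 (SE 0.224, edgeR adjusted p = 3.73e-16), and LOX4 fell further in leaf than in root by 1.42 (SE 0.113). The LHY genes were higher in root relative to leaf by 0.67 (SE 0.111) for LHY1a and 0.97 (SE 0.113) for LHY2b, whereas GIa did not differ past the threshold (-0.29, SE 0.145, edgeR adjusted p = 0.164). CHS7 had a difference of -1.48 (SE 0.149) and CHS8 of -1.14 (SE 0.122). RBCS2 fell in leaf and its difference was 1.05 (SE 0.198), and for RCA11 the difference of 0.55 missed the threshold (edgeR adjusted p = 0.0562). Tested members with a called difference were 12 of 18 clock and flowering genes, 6 of 12 flavonoid genes and 3 of 3 lipoxygenase genes. Among oil genes there were 1 of 10, and among nodulation genes 1 of 4. These totals include NINA and NFR5A, with 0 counts in leaf, and FT2A and E1, with 0 counts in root. Their differences could not be estimated, so the lack of a call says nothing about them. Of the genes behind the 8198, 3876 were called in leaf alone, 1718 in root alone, 1259 in both in the same direction, 1098 in both in opposite directions and 247 in neither. Among the opposite ones, Glyma.06G142000 (chromosome 6, 11559878 to 11562766) rose by 2.30 in leaf (SE 0.107) and fell by 1.20 in root (SE 0.0914). Glyma.05G070600 did the reverse, with -1.23 (SE 0.131) in leaf and 1.16 (SE 0.108) in root.

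WT root against WT leaf checks the tissue labels and gives a scale for the OE effects. The Rubisco genes marked the leaf, with RCA11 at 25970 ± 1160 CPM in WT leaf and 3.269 CPM in WT root (log2FC -12.95, SE 0.168, edgeR adjusted p = 2.82e-34) and RBCS2 at log2FC -11.39 (SE 0.17). CHS7 was higher in root by 6.57 (SE 0.116), CHS8 by 3.21 and IFS1 by 3.25, and 9 of 12 flavonoid genes were higher in root and 3 in leaf. Of the 18 clock and flowering genes, 4 were higher in root and 11 in leaf, among the latter LHY1a at -2.16 and LHY2b at -3.93. The 10 oil genes split into 5 and 5, with WRI1A at 2.57 and FAD2-2B at -3.93. Among all genes, 27956 (77.7%) passed in edgeR, 15043 higher in root and 12913 in leaf, and 19111 differed by at least 2-fold, against 4429 and 2710 for OE in leaf and root.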

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

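The count of close gene pairs and the test of gene length as the whole cause, below, were tests chosen only after the result was seen, as was leaving LUXB in leaf out of the test of time of day. The values per gene in the paragraphs on clock, flavonoid, lipoxygenase and other genes are differences of the OE effect (root minus leaf, log2) that passed the edgeR test of the difference itself.

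The difference passed for 8198 genes in all. Of 40 drawn splits of the libraries within the tissues, 1, the real one, gave as many. The highest other gave 5027, a split in which one tissue kept its real groups. Such splits mix OE and WT libraries and so also break any OE effect common to both tissues. They therefore cannot decide whether chance gave the count of differences. For leaf, the 6 libraries make 10 splits, too few for a share under 0.05, and 1 of them, the real one, reached 14544 genes with 0 as the highest other. Root also has 10 splits, too few likewise, with 10822 genes and a highest other of 0, reached by 1. For WT root against WT leaf, 1 of 10 reached 27956, with 0 as the highest other.

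Among clock and light genes, the effect was higher in root for LHY1a (0.67), LHY1b (0.50), LHY2a (0.66), LHY2b (0.97) and FT5A (3.51), the last on few root counts. It was lower in root for ELF3A (-0.69), LUXC (-0.93), PRR3B (-1.13), PHYA1 (-0.55), PHYA2 (-0.42), PHYA3 (-0.61) and CRY2a (-0.33). Flavonoid genes gave -1.48 for CHS7, -1.14 for CHS8, -0.56 for IFS1, -0.36 for CHI1A, -0.52 for MYB176 and 0.76 for IFS2. Lipoxygenase genes gave 1.42 for LOX4, 0.80 for LOX7 and 4.41 for LOX10. The values were 1.05 for RBCS2, -0.68 for FATB1a, -1.42 for the transcription factor gene WRKY27, 0.44 for the sodium antiporter gene NHX1 and -2.01 for NSP1, a regulator of nodulation with few leaf counts.

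Genes without a name gave -3.51 for Glyma.01G206600, 2.40 for Glyma.05G070600, -3.83 for Glyma.05G247800, -3.49 for Glyma.06G142000, -2.14 for Glyma.08G317400, -3.35 for Glyma.09G274000, 2.31 for Glyma.11G239200, 5.70 for Glyma.15G245300, 1.33 for Glyma.18G036400, -2.0 for Glyma.18G226300 and 3.92 for Glyma.20G196900. The fitted values of 7.20 for Glyma.12G184400 and 13.71 for Glyma.18G103500 rest on OE leaf at 0 counts and depend on the prior count.

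The first pattern weighed is the set of 207 genes that changed at least 4-fold in the same direction in both tissues, 187 down and 20 up. A library difference that lowers all genes of a given length alike is argued against as the whole cause of the 187 falls. Exon lengths of these 187 genes had an interquartile range of 1036 to 1986 bp. The 15277 tested genes of that range outside the set had a median log2FC of -0.03 in leaf and -0.04 in root. Scaling sets the bulk of the 35968 tested genes near 0, and these 15277 are a large part of it, so part of a shift could be hidden. Length may still have a part, because the 207 genes had a median exon length of 1496 bp where matched random sets had 1666 to 1956. Inherited chromosome segments that differ between OE-34 and Jack could also give such a set, and 46 pairs of these genes lay within 500 kb where random sets had 27 to 53, which leaves scattered differences open. The effect of GmZF351 itself, with 1 line in the design, cannot be separated from other differences of that line and stays open.

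The second pattern is the rise of GIa in both tissues. Harvest at another time of day might raise it, and the other evening-phased clock genes LUXB, LUXC, ELF3A and PRR3B would then rise as well. Their median log2FC was 0.1 over 7 values from -0.85 to 1.30, with a mean of -0.04. Values of the same gene in leaf and root are not independent, so an interval over them is rough and does not measure spread between replicates. By the t distribution the 95% interval over these values was -0.72 to 0.65, which includes the 0.5 set as the bound. With LUXB in leaf, 5 counts in all, the median was -0.25 and the upper bound 0.48, under that bound, but a gene at the floor decides nothing and the bound was wrong to admit it. Time of harvest and genotype cannot be told apart by these genes, which went both ways.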

How the results depend on the processing

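Only fits listed before the data were examined are given here, apart from the gene sets and the count of 4-fold changes shared by both tissues, which were chosen after seeing the data. With DESeq2 size factors, no filter, the 1 CPM filter, DESeq2 or fits on a single tissue, each count of calls stayed within 1.5 times its value. Calls ranged from 13941 to 14466 in leaf, 10597 to 11818 in root, 8083 to 8486 for the difference and 27102 to 28895 for WT root against WT leaf. A minimum of 2-fold change left 4429 genes in leaf in place of 14544, 2710 in root in place of 10822 and 3610 for the difference in place of 8198, and glmTreat left 5287 in leaf and 2826 in root, since both remove small changes by construction. The 207 genes changed 4-fold in both tissues became 138 in fits on a single tissue and 196 to 222 under the other settings. DESeq2 size factors gave 38.4% of leaf calls as rises against 45.4%. They gave 58.8% of difference calls as higher in root against 50.8%, as did DESeq2. Fits on a single tissue gave 45.7% of root calls as rises against 39.8%. Of the calls shared by both tissues in the same direction, these fits gave 43.1% as rises against 34.3%. With fry in place of camera the clock and flowering set in root had adjusted p = 0.014, against 0.13, and over single libraries left out camera gave 0.096 to 0.23. Fry, unlike camera, does not compare the set with other genes, and what else adds to the gap was not tested. No other call of a gene set changed.

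With 1 library left out, calls ranged from 12794 to 15357 in leaf, 8421 to 11503 in root, 6974 to 7980 for the difference and 27234 to 28149 for the tissues. The flavonoid set in root ranged from 0.00029 to 0.0014, and the GmZF351 log2FC from 15.55 to 18.42 in leaf and 13.71 to 17.6 in root, where 1 and 4 WT counts carry the ratio. Of 894 values for 152 results of named genes in single tissues under 6 other settings, 877 kept their side of the threshold, 17 passed newly and 0 were lost. With single libraries left out, 1770 of 1824 kept their side, 34 were lost and 20 passed newly. In both cases 0 reversed, counting changes of sign only where at least 1 of the fits compared passed the threshold. Values past it in neither fit could change sign, as CHI1A in leaf did with DESeq2 size factors.

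No sign of pairing by replicate number was seen, as deviations of same-numbered libraries correlated between -0.06 and 0.05. Such values cannot show that same-numbered libraries came from different plants, which the labels leave open. With the replicate block, calls were 14527 in leaf, 10807 in root, 8237 for the difference and 27240 for the tissues, 4677 genes overlapped in direction, 206 changed 4-fold in both, GmZF351 had log2FC 16.04 and 14.27, and the flavonoid set in root had adjusted p = 0.0014.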

Other observations

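The nodulation and stress genes in this part were written down after the files had been opened and before fold changes were computed, and the set changed at least 4-fold in both tissues was chosen after seeing the data.

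Genes of the symbiosis with rhizobia differed between genotypes in root. NINA (Glyma.04G000600, chromosome 4, 72328 to 75769), of the NODULE INCEPTION family of regulators that start nodule formation, rose 3.63-fold, from 2.593 ± 0.597 to 9.439 ± 1.03 CPM (SD, n = 3; log2FC 1.86, SE 0.221, edgeR adjusted p = 1.14e-07). The Nod factor receptor gene NFR5A (Glyma.11G063100) rose from 22.91 ± 1.69 to 31.91 ± 0.969 CPM (log2FC 0.48, SE 0.111). NARK, the receptor kinase gene that limits nodule number, had log2FC 0.38 (SE 0.113, edgeR adjusted p = 0.00929), which became 0.0538 without WT root replicate 2. NSP1 had -0.50 (SE 0.159, edgeR adjusted p = 0.0155), which ended without replicate 1 or 2 of either genotype, with adjusted p up to 0.0911 (without OE root replicate 1). So 3 of 4 tested members rose in root and 1 fell, 4 passed when adjusted over the list alone, and 0 of 4 passed in leaf, where NINA and NFR5A had 0 counts. With 4 members the set was too small for a set test.

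Among stress genes, the transcription factor gene WRKY27 (Glyma.15G003300) fell in root from 60.01 ± 2.17 to 24.27 ± 0.598 CPM (SD, n = 3; log2FC -1.31, SE 0.108, edgeR adjusted p = 1.31e-11) and had log2FC 0.11 in leaf (edgeR adjusted p = 0.588). The sodium transporter genes NHX1 and SOS1 had -0.25 (SE 0.0852) and -0.42 (SE 0.12) in leaf, and without OE leaf replicate 2 their edgeR adjusted p was 0.116 and 0.0567. The call of NHX1 also ended without OE leaf replicate 3 or WT leaf replicate 2. SHAT1-5 (Glyma.16G019400), a NAC gene known from pod shattering, fell by 0.61 in leaf (SE 0.147) and by 0.65 in root (SE 0.132). SNAP18 (Glyma.18G022500), at a locus for cyst nematode resistance, had -0.26 in leaf and -0.27 in root, and its edgeR adjusted p was 0.059 without OE leaf replicate 3 and 0.0639 without OE root replicate 2. The seed desaturase gene FAD2-1A had 18 counts in OE leaf and 4 in WT leaf over 3 libraries each and was not tested. Of the other untested oil genes, FAD2-1B, LEC1-A, LEC1-B, OLEO1 and SWEET24 had 0 counts in leaf. SWEET39 had 1 count in OE leaf and 0 in WT leaf.

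The 207 genes changed at least 4-fold in both tissues lay on all 20 chromosomes. Of the 187 that fell, 10 were at 1 CPM or more in WT and under 0.1 CPM in OE in both tissues, and of the 20 that rose, 3 besides GmZF351 showed the reverse.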
